A study of Mus musculus with 6 samples.

How the data were processed

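Polyadenylated RNA was measured in 6 libraries of mouse wild-type CD8+ T cells. Per the labels, the cells were sorted and activated with plate-bound anti-CD3 (1 µg/ml), anti-CD28 (1 µg/ml) and interleukin 2 (0.1 µg/ml) in RPMI with 10% fetal bovine serum. Conditioned medium was added at day 1 and RNA was taken at day 3. RNA was isolated with PicoPure, had a mean quality number of 9.4 (range 9.0 to 9.8), and 500 ng entered a directional NEBNext Ultra II preparation after selection of polyadenylated RNA.

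The deposited values are whole-number read counts per gene, 1 column per library, made by the authors. The submitters' processing notes name FastQC, TopHat2 2.0.10, Bowtie 1.0.0, SAMtools 0.1.19, Cufflinks 2.2.1 and the GRCm39 build. The program that made the counts, its gene annotation and its strand setting are not given in the sources used here, so counts of overlapping genes on opposite strands and of near-identical families such as the granzymes near Gzmc are less certain. The table held 14481 genes with a lowest gene total of 40 over the 6 libraries, so genes with lower counts were missing from it, and the filter that removed them is not stated. Of its gene names, 14121 matched symbols of the GRCm38 annotation held here, which gave transcript GC content, length and gene order, and no coordinates are reported. Reads were not analysed here.

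Total counts were 45321200, 47569899 and 43551518 in STAT3- CM and 47129785, 43346089 and 53630514 in STAT3+ CM. Mitochondrially encoded genes took 1.6% to 1.98% of the counts and the 10 most abundant genes 4.51% to 5.46%. The median biological coefficient of variation was 16.95%, and the median SE of a log2 fold change 0.18. The unit of replication was the library.

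Counts were filtered with filterByExpr, which kept 14319 genes and left out 162, and scaled by TMM factors of 0.9605 to 1.06. The groups were compared in edgeR 4.0.16 under R 4.3.3 by the robust quasi-likelihood F test of edgeR 4, while the installed version's default, the older method, was an alternative. P-values were two-sided and adjusted by Benjamini and Hochberg over all genes tested, with a threshold of 0.05. The SE is the absolute log2 fold change over the square root of F. Log2 CPM for components and scores used a prior count of 2. Gene lists with at least 5 tested genes, 35 of 37, were compared with other genes by camera in limma 3.58.1 with a preset correlation of 0.01, and adjusted over the 35. Camera with an estimated correlation and fry were run beside it. Camera with an estimated correlation also takes its degrees of freedom from the libraries rather than the genes. With 6 libraries it therefore has little power.

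The groups, comparison, gene lists, 23 panel genes and rule for named genes were fixed before the data were examined. The rule took up to 10 genes in each direction with the largest log2 fold change among those past the threshold, with groups that did not overlap a mean of at least 1 CPM in either group and a symbol that is not a predicted or clone name. It also took the 5 genes with the smallest p where fewer than 5 passed, the panel genes, and the 4 members of each list with the smallest p. Because edgeR gave no call, the first part was applied to the calls of DESeq2 1.42.0 after that was seen, and it chose 20 of 46 eligible genes. Other names, such as Tgm2, H2-Ab1, Itgax, Batf3 and the neighbours of Ccr9, were chosen after their values were seen. The set of 11 other retinoic acid genes was fixed before it was averaged or compared as a set, though 4 of them stand in lists whose medians had been seen. The genes singled out from that set were picked after their values were seen. Some genes that the rule names are not reported here.

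The alternatives were other scalings (RLE, upper quartile, library totals only), no filter or a stricter one (at least 1 CPM in at least 3 libraries), DESeq2, limma-voom with and without sample quality weights, the older quasi-likelihood method, the replicate number as a block, a log2 fold change of at least 1, removal of mitochondrially encoded genes, and each library left out in turn. A fit without the 2 outlying libraries and 1 with 1 surrogate variable (sva 3.50.0) were added after the data had been seen. The replicate numbers did not pair the libraries, with correlations across genes of -0.261, 0.281 and 0.182 for equal numbers after each group's mean was removed. No library was left out of the values reported. The workflow was tested on simulated data with 200 changed genes. There edgeR recovered 12.5%, 56.1% and 89.4% of genes changed 1.5-fold, 2-fold and 4-fold, with 20 false calls of 124, and DESeq2 22.4%, 67.2% and 84.85%, with 48 of 164. Both shares of false calls are above the nominal 5%. Of 34 unchanged lists 0 were called, but the simulated genes were drawn independently of each other. That count therefore cannot show how often lists of correlated genes are called wrongly. Among the lists called in the real data, the estimated correlation ran from -0.0371 for dendritic cell markers to 0.729 for G2 and M phase genes.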

Results

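Polyadenylated RNA of mouse CD8+ T cells, the lymphocytes that kill infected and tumour cells, was sequenced at day 3 of culture. Sorted wild-type cells were activated through CD3 and CD28 with interleukin 2 for 1 day. They then received conditioned medium (CM) from astrospheres, named in the labels as pSTAT3+ or pSTAT3-, for the last 2 days; pSTAT3 is the phosphorylated, active form of the transcription factor STAT3. Each medium had 3 libraries, called here STAT3+ CM and STAT3- CM, and no library from cells without CM was analysed here. Total counts ran from 43346089 to 53630514 per library over 14481 genes, of which 14319 were tested. Values are CPM, read counts scaled by library total and TMM factor, given as mean ± SD of 3 libraries per group, and log2 fold changes are STAT3+ CM minus STAT3- CM with the standard error (SE). Nothing in the labels says that replicates were separate mice or cultures, so the p-values measure only the spread between these samples.

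The cells of both groups had the transcripts of activated CD8+ T cells. Gzmb, the protease granzyme B of cytotoxic granules, stood at 5111 ± 1223 CPM in STAT3- CM and 6857 ± 593 in STAT3+ CM, and Cd8a at 847 ± 80.3 and 908 ± 138. The groups did not form separate clusters over all genes. On the first principal component, with 36.8% of the variance, the scores were -23.9, -16.4 and 39.6 in STAT3- CM and 16.3, -21.8 and 6.12 in STAT3+ CM. On the second, with 31.1%, they were 17.45, 8.67 and 17.07 in STAT3- CM and -38.1, -19.23 and 14.14 in STAT3+ CM. There STAT3+ CM replicates 1 and 2 lay below all STAT3- CM libraries, replicate 1 farthest out, and replicate 3 lay among them. Across genes, Pearson's r of log2 CPM was 0.983 to 0.994 for library pairs within a group and 0.980 to 0.993 for pairs across groups.

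**Figure D1:**
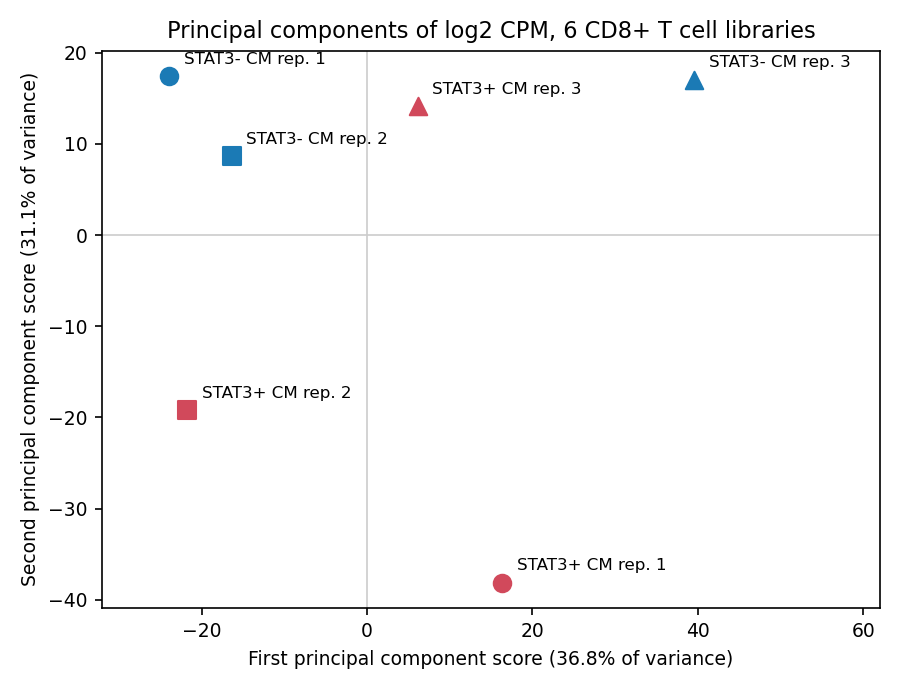
Scores of the 6 libraries on the first (x axis, 36.8% of variance) and second (y axis, 31.1%) principal components of log2 CPM; colours mark STAT3- CM (blue) and STAT3+ CM (red), and shapes mark replicates. STAT3- CM replicate 3 lies at 39.6 on the first component and STAT3+ CM replicate 1 at -38.1 on the second.

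The only comparison of the design asks how the secreted products of pSTAT3+ against pSTAT3- astrospheres affect gene expression in CD8+ T cells. The genes with the smallest p-values were lower in STAT3+ CM, but none passed the threshold. Dennd5a, a regulator of membrane traffic, stood at 84.5 ± 5.66 CPM in STAT3- CM and 43.7 ± 2.65 in STAT3+ CM (log2 fold change -0.95, SE 0.12, adjusted p = 0.0860). The carboxylesterase gene Ces2c, near the detection floor, stood at 0.586 ± 0.148 and 0.0581 ± 0.0193 CPM (log2 fold change -3.32, SE 0.47, adjusted p = 0.0860). Lgals3, which encodes the sugar-binding protein galectin-3, stood at 227 ± 25.1 and 80.2 ± 23.9 CPM, and the actin-severing Scin at 13.3 ± 1.88 and 4.79 ± 1.19, with log2 fold changes of -1.50 (SE 0.21, adjusted p = 0.103) and -1.47 (SE 0.22, adjusted p = 0.115). Gzmc, a granzyme gene with close relatives among which reads can be misassigned, stood at 45.0 ± 3.61 and 21.5 ± 3.37 CPM (log2 fold change -1.06, SE 0.15, adjusted p = 0.103). In each of these genes the 3 libraries of STAT3+ CM lay below all 3 of STAT3- CM.

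By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 0 of 14319 genes passed an adjusted p of 0.05. At an unadjusted p under 0.05 stood 521 genes, 192 higher and 329 lower in STAT3+ CM, where 5% of the genes tested is 716. DESeq2 called 48 genes, limma-voom 0 and limma-voom with sample quality weights 16. The 3 libraries of one group lay apart from the 3 of the other in 1139 genes, or 7.95%, where chance alone gives 10%. Without STAT3- CM replicate 3 edgeR called 18 genes, 15 of which DESeq2 also called, and without STAT3- CM replicate 1 it called Ccr9 alone. Without STAT3- CM replicate 3 and STAT3+ CM replicate 1 together, a pair left out after the principal components were seen, it called 10.

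DESeq2 called 48 genes in STAT3+ CM against STAT3- CM. Among its 15 higher genes, Ccr9, the receptor for the gut chemokine CCL25, had the largest log2 fold change by DESeq2, 2.34 (SE 0.56, adjusted p = 0.0129), from 5.78 ± 3.998 to 29.0 ± 6.34 CPM. P2rx7, an ATP-gated ion channel, had 1.39 (SE 0.32, adjusted p = 0.00732), the transcriptional repressor gene Hic1 1.025 (SE 0.22, adjusted p = 0.0035), and Dntt, the terminal transferase of V(D)J recombination, 1.48 (SE 0.38, adjusted p = 0.0332). The other higher genes taken by the rule for named genes were Enpep (2.10), Sorcs2 (1.76), Grtp1 (1.69), Dtx4 (1.26), Plac8 (1.07) and Lztfl1 (0.91). Among its 33 lower genes, Il9r, the interleukin 9 receptor, had a log2 fold change by DESeq2 of -1.87 (SE 0.34, adjusted p = 6.74e-05). Il1r2, the decoy receptor for interleukin 1, had -1.69 (SE 0.39, adjusted p = 0.00953), Rxra, the retinoid X receptor alpha, -1.60 (SE 0.36, adjusted p = 0.00649), and H2-Aa, a chain of MHC class II, -1.71 (SE 0.37, adjusted p = 0.00397). H2-Aa also stands among the dendritic cell markers described with the gene lists. The other lower genes taken by the rule were Adamtsl2 (-2.26), Pdzk1ip1 (-2.19), Pxdc1 (-1.85), Ifitm3 (-1.51), Ankrd33b (-1.51) and Lgals3 (-1.49).

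All 48 genes called by DESeq2 had an unadjusted edgeR p under 0.05 and no overlap between the groups, and 40 were among the 48 smallest edgeR p-values. The 20 named above were taken by the rule for named genes from DESeq2's calls after edgeR had given none. In simulated counts with 200 genes changed, 48 of DESeq2's 164 calls and 20 of edgeR's 124 were of unchanged genes. A split of the 6 libraries that put STAT3- CM replicates 1 and 2 and STAT3+ CM replicate 2 against the rest gave 248 DESeq2 calls.

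**Figure D2:**
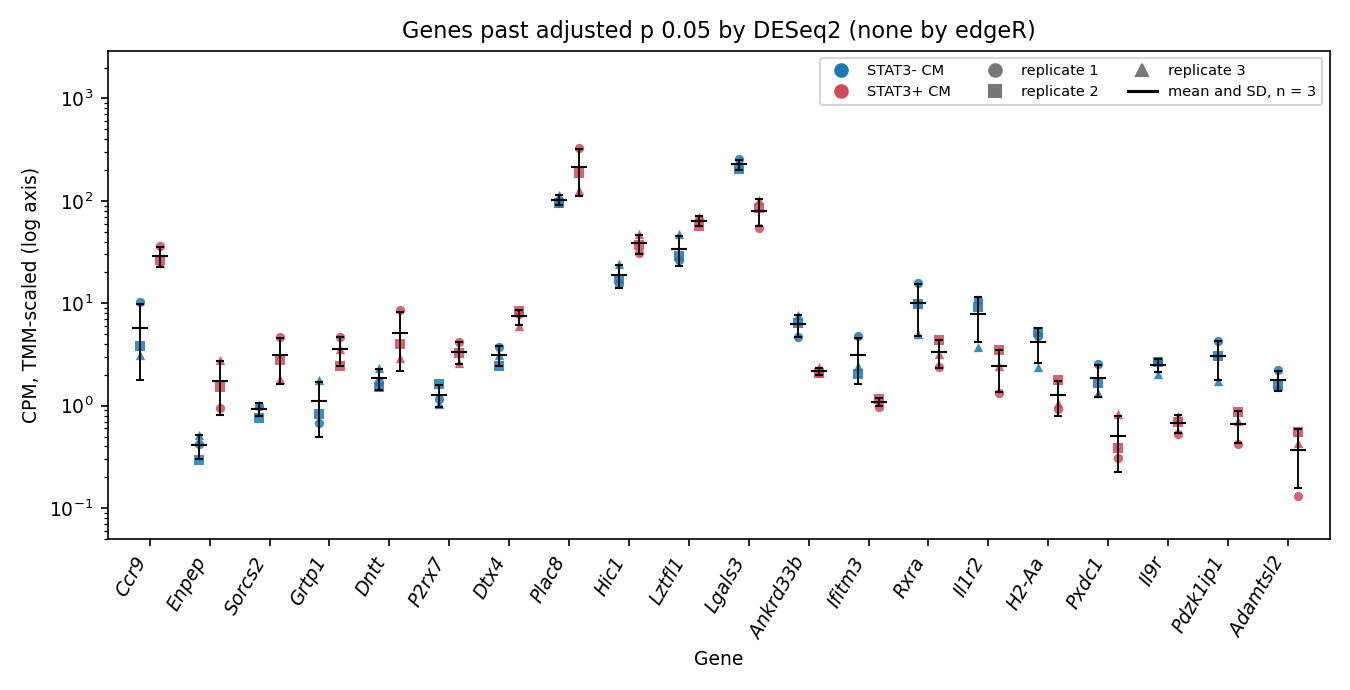
CPM (y axis, log scale) of 20 genes called by DESeq2, 10 higher and 10 lower in STAT3+ CM, in each of 6 libraries; blue marks STAT3- CM, red STAT3+ CM, shapes mark replicates, and bars give the mean and SD, n = 3. None of these genes passed by edgeR; in each the 2 groups do not overlap, as in Ccr9 with means of 5.78 and 29.0 CPM and Lgals3 with 227 and 80.2.

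Among cytotoxic and cytokine genes edgeR called none, and DESeq2 called Gzmc and Tnfsf10 lower and Lif higher in STAT3+ CM. Prf1, the pore-forming perforin, stood at 158 ± 8.07 CPM in STAT3- CM and 239.7 ± 75.4 in STAT3+ CM (log2 fold change 0.60, SE 0.20, adjusted p = 0.989 by edgeR), and Gzmb had a log2 fold change of 0.42 (SE 0.20, adjusted p = 0.989). Ifng stood at 915 ± 212 and 1023 ± 28.1 CPM, Tnf at 101 ± 34.9 and 127 ± 28.3, and Il2 at 65.5 ± 40.6 and 65.5 ± 26.6. Of 23 cytotoxic effector genes tested, 0 passed over all genes and 2 passed when adjusted over the list alone, both lower: Gzmc (adjusted p = 0.000599) and Tnfsf10, the death ligand TRAIL (log2 fold change -0.78, SE 0.19, adjusted p = 0.0233). The list's median log2 fold change was positive, 0.012, while its mean was -0.143 and the camera test pointed lower (adjusted p = 0.826). Among 24 cytokine and chemokine genes, 0 passed over all genes and 1 when adjusted over the list alone, Lif, the leukemia inhibitory factor, at 53.7 ± 6.98 and 95.9 ± 2.23 CPM (log2 fold change 0.84, SE 0.13, adjusted p = 0.00141). Lta (0.51), Csf1 (-1.27) and Ccl1 (-1.27) came next by p, and 18 of the 24 had positive values (camera, adjusted p = 0.0886). That list was called higher without STAT3- CM replicate 1 (adjusted p = 0.000219) or STAT3+ CM replicate 1 (0.000413), with a range of 0.000219 to 0.842 over 19 alternatives.

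Activation markers and inhibitory receptors showed no gene past the threshold. Cd69 stood at 193 ± 7.91 CPM in STAT3- CM and 220.3 ± 19.8 in STAT3+ CM, Il2ra, the high-affinity interleukin 2 receptor chain, at 766 ± 95.8 and 700.4 ± 97.4, and Cd44 at 256 ± 29.3 and 203 ± 60.1. Of 25 activation and costimulation genes 13 had positive log2 fold changes, led by p by Irf8 (0.54, SE 0.14), Cd83 (-0.55, SE 0.21), Egr3 (0.33) and Myc (0.21), and 0 passed over all genes or when adjusted over the list alone. Among inhibitory receptors, Pdcd1 (PD-1) stood at 129 ± 22.2 and 110.1 ± 29.9 CPM, Lag3 at 69.2 ± 29.2 and 70.2 ± 5.87, Havcr2 (TIM-3) at 21.8 ± 6.97 and 16.2 ± 1.85, Tigit at 50.2 ± 16.6 and 63.6 ± 13.7, and Ctla4 at 152 ± 136 and 171 ± 83.4. Of 23 genes on that list 10 had positive values, 0 passed over all genes and 0 when adjusted over the list alone. Nrp1 (-0.68, SE 0.25), Nt5e (0.35), Cd200r1 (-0.55) and Havcr2 (-0.42, SE 0.22) had its smallest p-values. Neither list stood apart from other genes (camera, adjusted p = 0.548 for each).

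Genes of naive and memory T cells were mostly on the positive side of 0, with none past the threshold. Tcf7, the transcription factor TCF-1, stood at 309.7 ± 38.4 CPM in STAT3- CM and 319 ± 47.6 in STAT3+ CM, and Il7r at 59.1 ± 29.1 and 59.8 ± 21.3. Of 24 genes 17 had positive log2 fold changes, with 0 past the threshold over all genes or when adjusted over the list alone. Il15ra (0.26), Cxcr5 (0.73), Id3 (0.38) and Igfbp4 (0.27) had the smallest p-values, and the list's camera adjusted p was 0.0532, with a range of 0.00986 to 0.5 over 19 alternatives. It was called higher in 9 of these, among them without STAT3- CM replicate 1 (0.0143), STAT3- CM replicate 3 (0.0311) or STAT3+ CM replicate 3 (0.0249). CD8 T cell identity genes stood higher in STAT3+ CM as a list, with 14 of 17 values positive and a median of 0.15 (camera, adjusted p = 0.0241), although 0 passed singly or when adjusted over the list alone; adjusted p = 0.87 with an estimated correlation. The dendritic cell markers stood lower as a list, with a median of -0.61 (camera, adjusted p = 0.000391, but 0.478 with an estimated correlation). The leading identity genes were the signalling chain Cd247 (0.25, SE 0.13), Cd3d (0.25), Cd8b1 (0.24, from 373 ± 23.2 to 441 ± 71.4 CPM) and Trac (0.21). That call was lost without STAT3- CM replicate 2 (adjusted p = 0.0689), STAT3- CM replicate 3 (0.103), STAT3+ CM replicate 1 (0.169) or STAT3+ CM replicate 2 (0.109), and over 19 alternatives its adjusted p ran from 0.0045 to 0.246. Relative to the mean of all libraries, the identity list's mean in STAT3+ CM replicate 3 (-0.0586) lay below STAT3- CM replicates 1 (-0.0368) and 3 (-0.0565).

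Targets of STAT3 in the T cells themselves did not stand apart. Stat3 stood at 289.8 ± 119.7 CPM in STAT3- CM and 260.2 ± 57.2 in STAT3+ CM, and its feedback inhibitor Socs3 at 19.6 ± 5.77 and 24.5 ± 6.85. Of 24 STAT3 target genes 11 had positive values, 0 passed over all genes or when adjusted over the list alone, and the camera adjusted p was 0.629. Among its smallest p-values were those of the transcription factors Rora (-0.75, SE 0.23), Ahr (-0.65, SE 0.26) and Maf (-1.18, SE 0.57). Of 20 STAT5 and interleukin 2 targets 11 had positive values and 0 passed over all genes or when adjusted over the list alone, with Lta (0.51), Prf1, Il4ra (0.28) and Tnfrsf8 (0.47) first by p. That list's camera adjusted p was 0.0886, and over 19 alternatives it ran from 0.0156 to 0.447 and was called higher in 3, DESeq2 (0.0156), limma-voom (0.0442) and limma-voom with quality weights (0.0268).

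Timp1, an inhibitor of metalloproteinases, was close to the detection floor in the T cells, at 0.785 ± 0.512 CPM in STAT3- CM and 0.159 ± 0.045 in STAT3+ CM (log2 fold change -2.26, SE 0.58). Its receptor Cd63 stood at 11.6 ± 4.99 and 17.2 ± 5.68 CPM (0.58, SE 0.33). Of 12 genes in the TIMP1 and CD63 list 10 had negative values, Cd44 (-0.33) and Cd82 (-0.21) among them. Over all genes 0 passed, and Timp1 was the 1 that passed when adjusted over the list alone (adjusted p = 0.0337 by edgeR). The camera adjusted p was 0.0518, and over 19 alternatives it ran from 0.015 to 0.779 and passed in 8, among them without STAT3+ CM replicate 2 (0.015) or STAT3+ CM replicate 3 (0.0345).

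Homing receptors went both ways. Of 25 homing and adhesion genes 12 had positive and 13 negative values, and 0 passed over all genes. Adjusted over the list alone 2 passed, Ccr9 on the higher side (log2 fold change 2.33, SE 0.38, adjusted p = 0.00327 by edgeR) and Ccr6, the receptor for CCL20, on the lower (-1.38, SE 0.37, adjusted p = 0.0477). Itgae (CD103) had -0.88 (SE 0.31) and Ccr4 -0.69 (SE 0.27). Of 19 TGF-beta response genes 0 passed over all genes and P2rx7 was the 1 that passed when adjusted over the list alone (log2 fold change 1.37, SE 0.29, adjusted p = 0.0149), followed by Cdkn2b (-1.99, SE 0.62), Itgae and Smad3 (0.39, SE 0.16). Neither list stood apart from other genes (camera, adjusted p = 0.629 and 0.729).

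**Figure D3:**
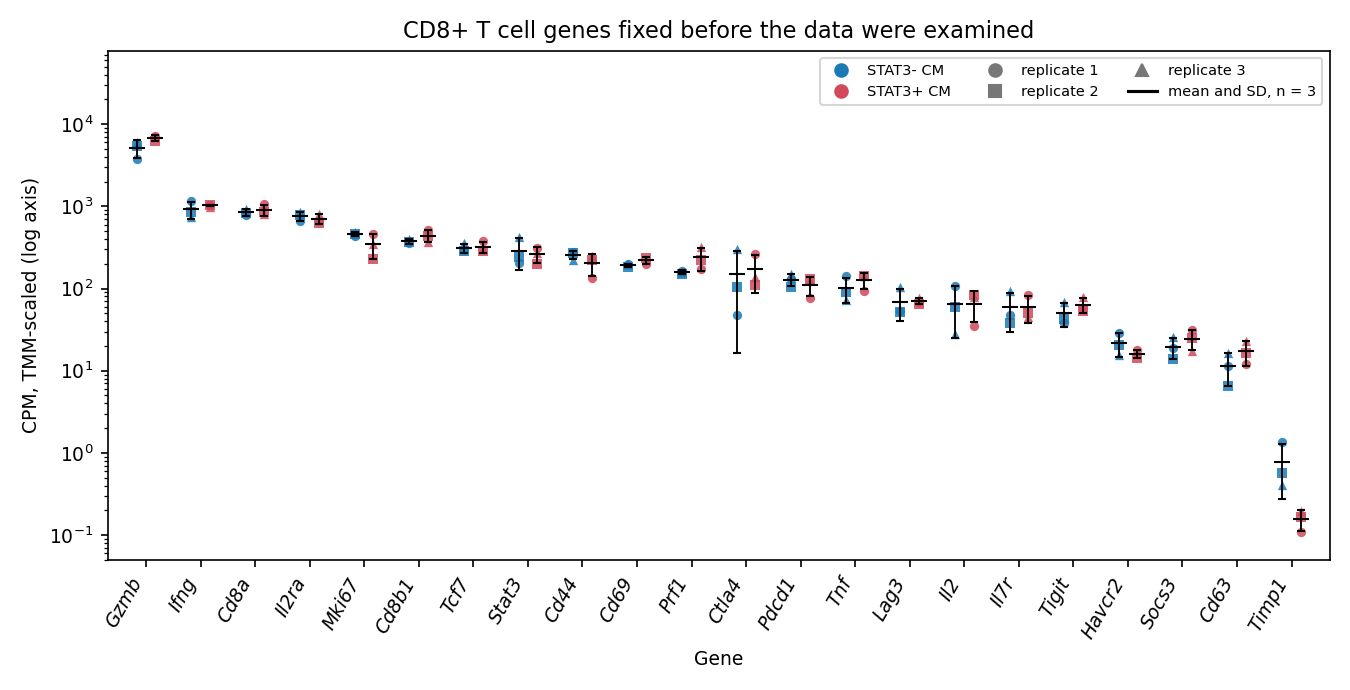
CPM (y axis, log scale) of genes chosen before the data were examined, in each of 6 libraries; blue marks STAT3- CM, red STAT3+ CM, shapes mark replicates, and bars give the mean and SD, n = 3. None passed by edgeR; Gzmb had means of 5111 and 6857 CPM and Timp1, the lowest, 0.785 and 0.159.

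Interferon-stimulated genes stood higher in STAT3+ CM as a list. Of 35 type I interferon response genes 29 had positive log2 fold changes, with a median of 0.37, and the list stood above other genes (camera, adjusted p = 6.71e-06). Its leading members were the antiviral genes Oas2 (1.05, SE 0.35), Ifit2 (0.38, SE 0.16), Oasl2 (1.08, SE 0.47) and Rsad2 (1.00, SE 0.47), and 0 passed singly or when adjusted over the list alone; adjusted p = 0.87 with an estimated correlation. Genes of interferon gamma response and antigen presentation had 25 of 30 values positive and a median of 0.14 (camera, adjusted p = 0.0148), and again 0 passed singly or when adjusted over the list alone; adjusted p = 0.87 with an estimated correlation. H2-T23 (0.29, SE 0.14), Psmb9 (0.29, SE 0.16) and Irf1 (0.31, SE 0.20) lay above 0, and Ciita, the class II transactivator, below it (-1.56, SE 0.59), beside lower values of the dendritic cell markers. The mean of the type I genes was lowest in STAT3- CM replicate 3, 0.61 below the mean of all libraries on the log2 scale. The groups overlapped, as STAT3+ CM replicate 3 (-0.216) lay below STAT3- CM replicates 1 (0.159) and 2 (-0.163) on that scale. Without STAT3- CM replicate 3 the type I adjusted p was 0.057 and the interferon gamma list turned lower with 0.837. Over 19 alternatives the type I adjusted p ran from 7.17e-13 to 0.778, and the interferon gamma call was also lost without STAT3+ CM replicate 1 (0.249) or replicate 2 (0.294), with a range of 3.17e-05 to 0.837.

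Markers of dendritic cells, which the sort for CD8+ T cells should remove, stood lower in STAT3+ CM as a list, although only 7 of its 14 genes could be tested. Of 7 genes tested 6 had negative values, with a median of -0.61 (camera, adjusted p = 0.000391), and 0 passed singly over all genes; adjusted p = 0.478 with an estimated correlation. Adjusted over the list alone 4 passed by edgeR, all lower: H2-Aa (log2 fold change -1.74, SE 0.37), the class II invariant chain Cd74 (-0.94, SE 0.21, from 74.7 ± 22.1 to 39.0 ± 4.98 CPM), H2-Eb1 (-0.88, SE 0.23) and the transcription factor Zbtb46 (-0.61, SE 0.22). Itgax (-0.04) and Batf3 (-0.14) lay nearer 0. H2-Ab1, the partner chain of H2-Aa, did not share their direction, at 7.50 ± 2.06 and 8.21 ± 0.496 CPM (0.13, SE 0.22). The list's call held in each of 19 alternatives, with adjusted p from 8.21e-08 to 0.0223. It rests largely on MHC class II genes, as Flt3, Clec9a, Xcr1, Siglech, Cd209a and Clec10a were absent from the deposited genes.

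Markers of other cell types did not stand apart with all libraries. Macrophage and microglia markers (7 tested, median 0.16, camera adjusted p = 0.638), B cell markers (5, 0.10, 0.395), CD4 T cell markers (8, -0.19, 0.629), natural killer and innate-like markers (10, -0.08, 0.638), fibroblast and endothelial markers (5, -0.18, 0.729) and astrocyte markers (7, 0.07, 0.729, with a mean of -0.03 and a test that pointed lower) had 0 genes past the threshold over all genes or when adjusted over the list alone. Without STAT3- CM replicate 3 and STAT3+ CM replicate 1 together the natural killer list was called lower (adjusted p = 0.0248, range 0.0248 to 0.793). Several markers were scarce. Lyz2 stood at 0.619 ± 0.429 and 0.446 ± 0.322 CPM, Igkc at 0.931 ± 0.319 and 1.05 ± 0.304, and Klrb1f at 0.754 ± 0.237 and 0.476 ± 0.0714. Ighm was abundant and alike in both groups, at 296 ± 25.9 and 318 ± 20.4 CPM. Neutrophil and erythroid markers had too few tested genes for a list test, namely Cxcr2 (-0.21), Epor (-0.04) and Car2 (-0.99, SE 0.33), and Car2 was the 1 that passed when adjusted over the list alone (adjusted p = 0.0246 by edgeR).

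Targets of NF-kB stood lower in STAT3+ CM as a list, beside the lower dendritic cell markers. Of 19 genes 14 had negative values, with a median of -0.15 (camera, adjusted p = 0.0128), and 0 passed singly or when adjusted over the list alone; adjusted p = 0.87 with an estimated correlation. The chemokine gene Ccl22 (-1.90, SE 0.49), Cd83 (-0.55, SE 0.21), Nfkb2 (-0.28, SE 0.15) and Nfkb1 (-0.23, SE 0.13) led it. Dendritic cells also express Ccl22 and Cd83, but Cd83 stands on the T cell activation list too, and which cells the transcripts came from was not tested. The call was lost without STAT3- CM replicate 1 (adjusted p = 0.119) or STAT3+ CM replicate 1 (0.292), and over 19 alternatives it ran from 0.000382 to 0.292.

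Genes of amino acid supply and the integrated stress response stood lower in STAT3+ CM as a list. Of 29 genes 24 had negative values, with a median of -0.15 (camera, adjusted p = 6.64e-05); adjusted p = 0.87 with an estimated correlation. Over all genes 0 passed, and 3 passed when adjusted over the list alone by edgeR: the stress-induced regulator Nupr1 (log2 fold change -1.10, SE 0.25), the cystine transporter Slc7a11 (-0.91, SE 0.22) and the neutral amino acid transporter Slc1a4 (-0.48, SE 0.13). Sesn2 had -0.52 (SE 0.18). Among 21 NRF2 and oxidative stress genes, 0 passed over all genes, and Slc7a11 and the quinone reductase Nqo1 (-1.11, SE 0.29) were the 2 that passed when adjusted over the list alone, with Me1 (-1.07, SE 0.40) and Srxn1 (-0.998, SE 0.40) next (camera, adjusted p = 0.0799). The NRF2 list was called lower without STAT3- CM replicate 3 (adjusted p = 0.000192) or STAT3+ CM replicate 2 (0.0193), with a range of 0.000145 to 0.727. The amino acid list lost its call without STAT3+ CM replicate 3 (adjusted p = 0.0517) and held in the other 18 of 19 alternatives, from 1.86e-07.

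Genes of energy metabolism stood slightly higher in STAT3+ CM as lists. Nuclear genes of oxidative phosphorylation had 31 of 32 values positive with a median of 0.13 (camera, adjusted p = 0.000154; adjusted p = 0.87 with an estimated correlation), led by Ndufa5 (0.38, SE 0.14), Cycs (0.35, SE 0.14), Ndufb3 (0.29) and Cox6c (0.22). Mitochondrially encoded genes had 11 of 13 positive with a median of 0.14 (adjusted p = 0.0148; adjusted p = 0.87 with an estimated correlation), led by mt-Co2 (0.42, SE 0.18), mt-Nd3 (0.43), mt-Nd1 (0.30) and mt-Co3 (0.30), and glycolysis genes 19 of 23 with a median of 0.08 (adjusted p = 0.0429; adjusted p = 0.87 with an estimated correlation), led by the lactate exporter Slc16a3 (0.52, SE 0.18), Galk1 (0.37), Pdk1 (0.35) and the glucose transporter Slc2a3 (0.26). In these lists 0 genes passed over all genes or when adjusted over the list alone. The leading mitochondrially encoded genes differed widely in level. In STAT3- CM and STAT3+ CM, mt-Co3 stood at 1.14 and 1.42 CPM and mt-Nd3 at 2.88 and 3.90. By contrast, mt-Co2 stood at 29.1 and 39.0 CPM and mt-Nd1 at 2390 and 2936. Why some were so low was not tested. Among 26 hypoxia response genes 15 had positive values and 0 passed over all genes, while the lipid droplet gene Plin2 (0.64, SE 0.15) and the oxygen sensor Egln3 (0.86, SE 0.23) passed when adjusted over the list alone by edgeR, ahead of Ndrg1 (-0.60) and Kdm3a (-0.25). The hypoxia list's camera adjusted p was 0.136, and 0.011 without STAT3- CM replicate 2, with a range of 0.011 to 0.657 over 19 alternatives. Without STAT3- CM replicate 3 the adjusted p was 0.0546 for nuclear oxidative phosphorylation genes, 0.196 for mitochondrially encoded genes and 0.496 for glycolysis; over the alternatives these ran from 7.93e-08 to 0.181, 0.00109 to 0.196 and 0.000668 to 0.778. Without STAT3+ CM replicate 2 they were 0.084, 0.0648 and 0.084, the mitochondrially encoded call was also lost without STAT3+ CM replicate 3 (0.144), and glycolysis without STAT3- CM replicate 1 (0.15) or STAT3+ CM replicate 1 (0.204). Library means of the nuclear oxidative phosphorylation genes, relative to the mean of all libraries, overlapped. STAT3+ CM replicate 3 (-0.114) lay below STAT3- CM replicates 1 (-0.0671) and 2 (0.00241).

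Cell cycle genes of G2 and M phase stood slightly lower in STAT3+ CM as a list. Of 30 genes 25 had negative values, with a median of -0.10 (camera, adjusted p = 0.0241), and 0 passed singly or when adjusted over the list alone; adjusted p = 0.87 with an estimated correlation. The proliferation marker Mki67 stood at 464.5 ± 24.9 CPM in STAT3- CM and 344 ± 112.7 in STAT3+ CM (-0.43, SE 0.21), ahead of Foxm1 (-0.31), Cenpf (-0.33) and Cenpe (-0.27). G1 and S phase genes had 18 of 30 positive values, 0 past the threshold over all genes or when adjusted over the list alone, and a camera adjusted p of 0.629, with Rfc4 (0.24), Dut (0.22), Uhrf1 (-0.18) and Ccne1 (0.13) first by p. Without STAT3- CM replicate 2 the G1 and S list was called higher (adjusted p = 0.0117, range 0.0117 to 0.901), and without STAT3- CM replicate 3 and STAT3+ CM replicate 1 together it was called lower (0.0156). The G2 and M call was lost without STAT3- CM replicate 2 (adjusted p = 0.54), STAT3+ CM replicate 2 (0.686) or STAT3+ CM replicate 3 (0.747), with a range of 2.99e-11 to 0.747 over 19 alternatives. The list's mean was highest in STAT3+ CM replicate 1, 0.28 above the mean of all libraries, and lowest in STAT3+ CM replicate 2, at -0.28.

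**Figure D4:**
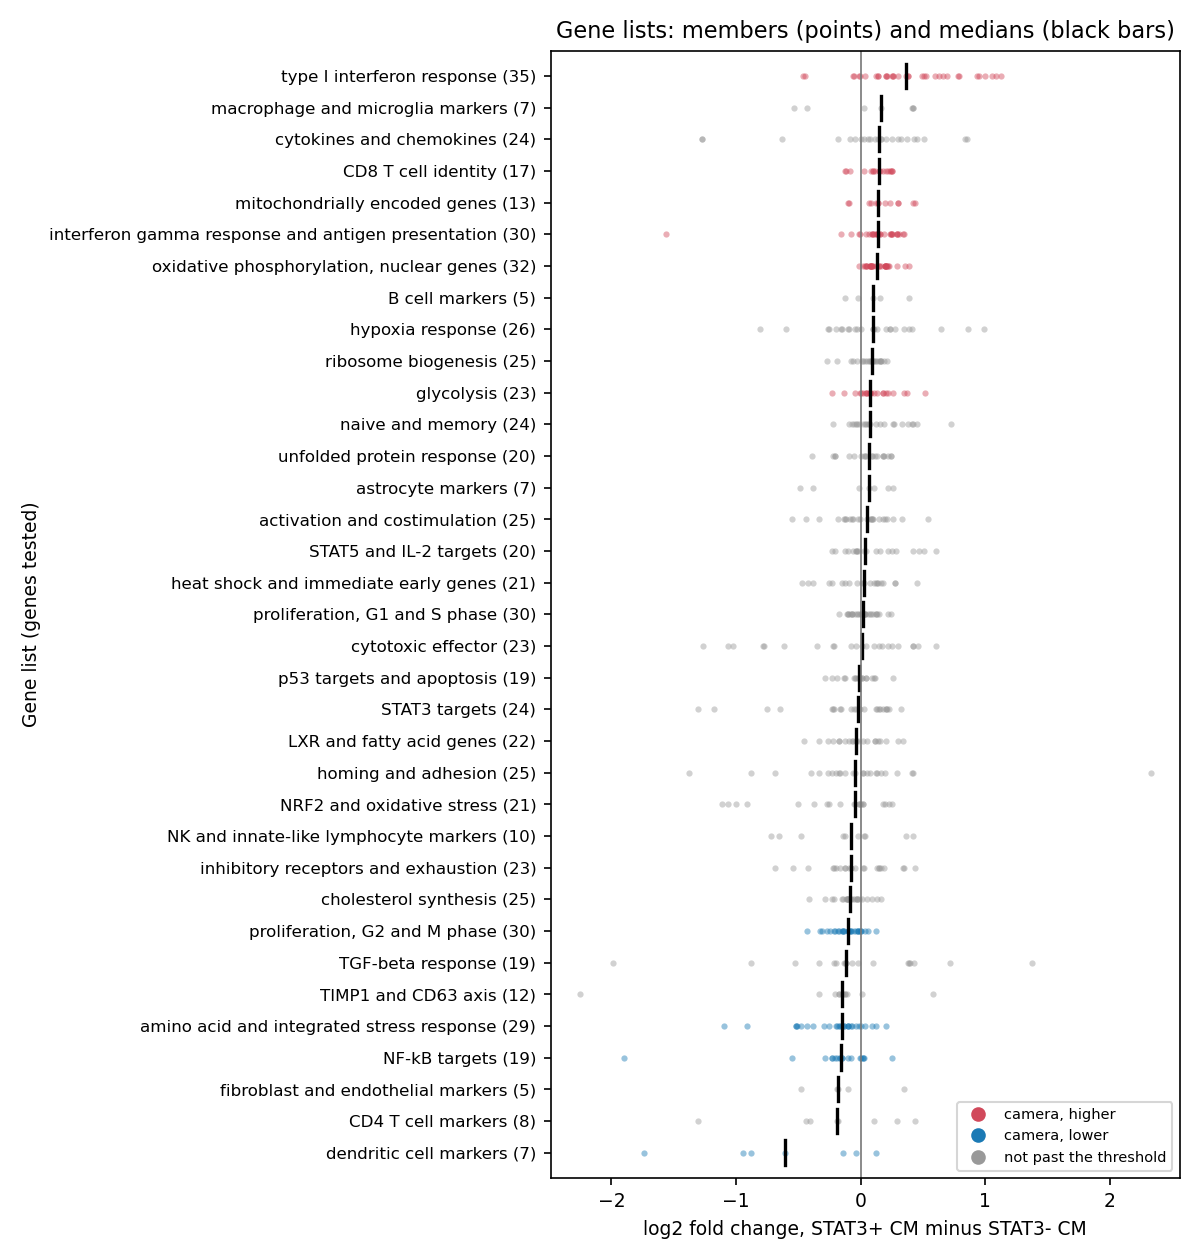
Log2 fold change, STAT3+ CM minus STAT3- CM (x axis), of the members (points) and medians (black bars) of 35 gene lists (y axis, with the number of genes tested); red and blue mark lists that camera with a preset correlation placed higher or lower, and grey the rest. The medians run from -0.61 for dendritic cell markers to 0.37 for type I interferon response, and no list passed with an estimated correlation.

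Of the 35 lists tested, camera with a preset correlation called 10, 6 higher and 4 lower in STAT3+ CM. With an estimated correlation 0 were called, and fry, which tests whether the genes of a list move one way on balance, called 0, with a smallest adjusted p of 0.121. The 0 calls with an estimated correlation do not show that correlation between genes made the 10 calls. That test takes its degrees of freedom from the 6 libraries, so it could pass few lists. For dendritic cell markers the estimated correlation of -0.0371 lay below the preset 0.01, yet camera's adjusted p went from 0.000391 to 0.478. Of 669 list members tested 0 passed over all genes and 18 when adjusted over the list alone. The latter adjustment was made within each of the 37 lists and not across them, so it is the more lenient. Another split of the 6 libraries gave 13 list calls.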

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

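The fits without the 2 outlying libraries and with 1 surrogate variable were chosen only after the data were seen. The count of 0 genes by edgeR, with 521 at an unadjusted p under 0.05 in that fit, held under each scaling, both filters, limma-voom, the older quasi-likelihood method, removal of mitochondrially encoded genes, a log2 fold change of at least 1 and the replicate block. DESeq2 called 48 genes (15 higher, 33 lower), 11 of them list members. Limma-voom with quality weights called 16 (6 higher, 10 lower; 4 list members), 15 shared with DESeq2, and 38 list members adjusted over the list alone in place of 18. With 1 surrogate variable 25 genes passed (5 higher, 20 lower; 7 list members), 22 shared with DESeq2, and 34 list members adjusted over the list alone. Without the 2 outlying libraries 10 passed (3 higher, 7 lower; 1 list member), 7 shared with DESeq2, and 51 adjusted over the list alone. There the interferon gamma list turned lower (adjusted p = 0.2), as it did without STAT3- CM replicate 3 (0.837, range over alternatives 3.17e-05 to 0.837), and the G1 and S phase list was called lower (0.0156). Leaving out 1 library in turn gave 0 to 18 genes, 0 to 3 higher and 0 to 15 lower, 6 to 12 lists, 0 to 3 list members over all genes and 6 to 46 adjusted over the list alone. The highest gene counts, 18, and 46 members, came without STAT3- CM replicate 3, which also left 6 lists. Without STAT3+ CM replicate 2, 6 lists and 6 members passed, without STAT3- CM replicate 1 1 gene, Ccr9, and 8 members, and without STAT3- CM replicate 2 11 members. A log2 fold change of at least 1 left 8 members. The replicate block gave 0 genes and 11 lists. Of 10 lists, 0 were called with an estimated correlation, 0 by fry and 0 by fry mixed, which tests for change in either direction. With quality weights the calls of interferon gamma (adjusted p = 0.336), mitochondrially encoded (0.0506) and glycolysis genes (0.129) were lost. Over 193 named genes and their alternatives, 72 of 3640 values changed sign, in 30 genes, and 84 were newly called. The settings with fewer libraries fit fewer values, and the cause of the other changes was not tested. With 3 libraries a group, changes of 1.5-fold were mostly missed in simulated counts (12.5% recovered by edgeR).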

Other observations

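The splits of the libraries, the tests of H2-Ab1, of single libraries and of sequencing depth were chosen only after the results were seen, and the patterns weighed here were themselves noticed in these data. Lipid genes lay mostly below 0 in STAT3+ CM without passing. Of 25 cholesterol synthesis genes 20 had negative log2 fold changes, with Lss (-0.28, SE 0.14), Idi1 (-0.22) and Fdft1 (-0.15) among the first by p (camera, adjusted p = 0.133). The cholesterol list was called lower without STAT3- CM replicate 1 (adjusted p = 0.00337) or STAT3+ CM replicate 1 (0.0151), with a range of 0.00337 to 0.984 over 19 alternatives. Of 22 LXR and fatty acid genes 13 were negative, among them Fasn, the fatty acid synthase, at 426 ± 124 CPM in STAT3- CM and 311 ± 42.1 in STAT3+ CM (-0.45, SE 0.21), Acaca (-0.33) and Acly (-0.17), with Elovl6 above 0 (0.30) (camera, adjusted p = 0.826). Over all genes and adjusted over the list alone 0 of either list passed by edgeR.

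Other stress and growth lists did not stand apart, and 0 of their genes passed over all genes or adjusted over the list alone by edgeR. The unfolded protein response had 13 of 20 values positive (adjusted p = 0.548; Ern1 -0.39, Sdf2l1 0.24, Sel1l -0.21, Herpud1 -0.21) and p53 targets 8 of 19 (0.629; Pmaip1 -0.23, Bbc3 -0.29, Gtse1 -0.19, Cdkn1a 0.26). Ribosome biogenesis genes had 20 of 25 (0.136; Polr1a -0.19, Utp20 -0.27, Nhp2 0.21, Fbl 0.15) and were called higher without STAT3- CM replicate 1 (adjusted p = 0.0143), STAT3- CM replicate 2 (0.000668) or STAT3+ CM replicate 1 (0.0151), with a range of 0.000668 to 0.849. Heat shock and immediate early genes had 12 of 21, with a median of 0.03, a mean of -0.01 and a test that pointed higher (0.594). Its first gene by p was the AP-1 subunit Jun, at 48.4 ± 2.45 and 66.3 ± 3.78 CPM (0.45, SE 0.12, adjusted p = 0.0596 by edgeR, adjusted over the list alone). Lztfl1 (0.91) and Ccr9 (2.33) are neighbours in the GRCm38 gene order, and the nearest other tested genes, Sacm1l (0.05, SE 0.13), Fyco1 (-0.44, SE 0.37) and Cxcr6 (-0.12, SE 0.38), had values near or below 0.

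The lower MHC class II transcripts in STAT3+ CM may come from fewer residual antigen-presenting cells, which the sort should remove, or from less of the transactivator Ciita in the T cells. H2-Ab1 did not share the lower values: it differed by 0.167 (SE 0.251) on the log2 scale, against a mean of -0.815 (SE 0.205) over H2-Aa, H2-Eb1, Cd74 and H2-Ab1. As H2-Ab1 was picked after its value was seen and is part of that mean, this is no separate test of a loss shared by all class II genes. For H2-Aa, H2-Eb1 and Cd74, 11 antigen-presenting cell genes outside class II differed by -0.139 (SE 0.173), within 2 SE of both 0 and the predicted bound of -0.408. That bound came from the mean that includes H2-Ab1. A bound from the 3 lower genes alone would lie farther below 0 and could turn the result against fewer such cells. It was not computed. The 11 genes went both ways by edgeR. Cd40 (-1.67, SE 0.56) and Cst3 (-0.30, SE 0.12) lay below 0, and Cd86 (0.63, SE 0.35) and Mpeg1 (0.55, SE 0.45) above. Dendritic cell markers such as Flt3, Clec9a and Xcr1 were absent from the deposited genes and could not be compared. Ciita differed by -1.2 (SE 0.848) in log2 CPM, the measure the test used, beyond the bound of -0.408 but within 2 SE of 0. Its edgeR log2 fold change of -1.56 (SE 0.59, adjusted p = 0.989) lay beyond the bound and more than 2 SE below 0, as the prediction asked. The measures thus disagree on Ciita, and neither decides it. Ciita was scarce and its groups overlapped, at 1.72, 1.83 and 0.303 CPM in STAT3- CM and 0.264, 0.504 and 0.524 in STAT3+ CM. Which cells its transcripts came from was not tested. Both sources stay open and cannot be told apart for these 3 genes.

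Ccr9, Hic1, P2rx7 and Tgm2, genes known to respond to retinoic acid, all had positive log2 fold changes, and a retinoic acid response in the T cells was a candidate explanation. The mean difference of 11 other retinoic acid genes was 0.0259 (SE 0.0821), more than 2 SE below the bound of 0.514. By the rule set beforehand this counted against the explanation. Their median log2 fold change of -0.05, with 5 of 11 positive, stood at percentile 24 of 10000 matched random lists. No shared rise was seen. The rule was then set aside because the genes went both ways, a step that was not part of the rule. Dhrs3 (0.68, SE 0.30), Cd38 (0.44, SE 0.40) and Crabp2 (0.41, SE 0.21) lay above 0 and Asb2 (-0.56, SE 0.21) and Rarg (-0.39, SE 0.19) below. A mean over such genes decides little, so the explanation stays open. Ccr9, Hic1 and P2rx7 kept at least 82.7% of their log2 fold change without any 1 STAT3+ CM library, which decides nothing, since they were taken because their groups did not overlap. Tgm2 (1.05, SE 0.70), which was not called, kept 48.35% without STAT3+ CM replicate 1, as a single library would predict, but 135.8% without STAT3+ CM replicate 3. It varied widely in both groups, which overlapped, at 30.1, 9.56 and 3.18 CPM in STAT3- CM and 48.15, 28.6 and 12.3 in STAT3+ CM.

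The libraries spread along the first principal component across both groups, and another structure than the medium may underlie it: the split of STAT3- CM replicates 1 and 2 and STAT3+ CM replicate 2 against the rest follows the sign of its scores and called 248 genes by DESeq2 and 0 by edgeR (1952 at an unadjusted p under 0.05), which points to a structure of the samples but, as the same libraries define the component, is no separate evidence of it. Sequencing depth stays open. With 6 libraries the Spearman rho of 0.143 with total counts (exact permutation p = 0.803, adjusted 0.803) cannot be told from a strong one. The Pearson r was 0.0345 (exact permutation p = 0.94, adjusted 0.94). It was -0.53 without STAT3+ CM replicates 2 and 3, the 2 libraries farthest from the median total count. The other of 2 relations computed, with the mitochondrial share, gave rho -0.543 (exact permutation p = 0.297, adjusted 0.594). Its r was -0.362 (exact permutation p = 0.493, adjusted 0.94). Without STAT3+ CM replicates 2 and 3, also the farthest from the median share, r was -0.826. GC content was argued against by a rho of 0.028 with the gene loadings across genes, which are not independent replicates, while transcript length, with a rho of 0.187, stays open. No biological explanation was tested.

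The 10 splits of the 6 libraries are too few for a share under 0.05. For edgeR the real count was 0 (521 at an unadjusted p under 0.05) and the highest other 0, and that 10 of 10 splits reached 0 was fixed in advance and shows nothing. DESeq2's 48 was reached in 2 of 10, with 248 the highest other, and the 10 lists called by camera in 5 of 10, with 13 the highest other. The 25 genes with 1 surrogate variable were reached in 1 of 10, the real split, with 3 the highest other.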
